A study of Mus musculus with 6 samples.

How the data were processed

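RNA was measured in 6 mouse bone marrow samples, 3 from vehicle-treated and 3 from inhibitor-treated recipients of Dnmt3a knockout marrow. Per the labels' protocols, RNA was purified with a column kit for small samples, full-length cDNA was made with a SMART-Seq v4 ultra-low input kit and libraries with Nextera XT, a chemistry that does not mark strand. Per the submitters' processing notes, reads were aligned with STAR to mm10 and counted with featureCounts (versions not given in the sources used here). The authors deposited 1 table of 14992 genes with raw read counts per gene and library. Whether genes were filtered before deposit is not given in the sources used here. The same deposited table holds, per the file headers, the length of each gene in bases, and the authors' own comparison as a fold change (a ratio), a log2 fold change, a p-value and an adjusted p-value, with the test behind them not given in the sources used here. There, 15 genes have no p-value and 1168 a p-value but no adjusted one. The 14992 empty lines between genes were dropped.

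Samples were grouped by the treatment in the labels. Total counts ran from 28198638 to 59384880 per library. Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (12806 genes tested, 2186 left out), TMM scaling, and the quasi-likelihood F test (glmQLFit and glmQLFTest) on group alone, with Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 25.2%. The standard error of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes.

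The test, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined. Genes are named by 3 parts of that rule: Dnmt3a and 4 PI3K catalytic genes always; the 10 largest fold changes in each direction among genes past the threshold with a mean of at least 5 CPM, no overlap between groups and a regular symbol (57 higher and 126 lower genes qualified); and in each list up to 4 members with the smallest p and every called member where there are 6 or fewer. Some genes that meet the rule were tested and counted but are not reported here by name. Genes named in the closing section outside this rule were chosen after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 (limma 3.58.1), with camera at an estimated correlation, and with fry, which asks only whether the genes of a list move. A list of mitochondrially encoded genes had 0 members in the table and was not tested. The cell type lists were macrophage, monocyte, MHC class II, neutrophil primary and late granule, B lymphoid, plasma cell, T and NK cell, basophil, mast cell and eosinophil, dendritic cell, erythroid, heme synthesis, megakaryocyte, stem and progenitor cell, and stroma. The others were pathway lists: PI3K components, FOXO targets, SREBP, ATF4, MYC, glycolysis, oxidative phosphorylation, ribosomal proteins, interferon, NF-kB, immediate early genes, unfolded protein response, p53, mitosis, DNA replication and DNA methylation. List scores are means of log2(CPM + 1) over members, compared by an exact two-sided permutation test whose smallest p is 0.1 for 3 against 3.

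Sex-linked genes were read as a sample check: every library held Y-linked transcripts and at most 2 counts of Xist. No pair of libraries was a duplicate, since the chi-square per degree of freedom between vehicles 2 and 3, the closest pair, was 31.1. Across genes, log2 fold change and gene length had a Spearman correlation of -0.151, and genes are not independent replicates. The steps were tested on simulated data for this comparison: in 5 runs over 12806 genes with 200 changed genes each, edgeR recovered 2.4% of 1.5-fold, 35.2% of 2-fold, 80.8% of 4-fold and 92.4% of 8-fold changes with 5.22% of its calls false. DESeq2 recovered 14.4%, 60.0%, 90.0% and 94.0% at the same folds with 23.4% of its calls false. Camera called 5 of 5 raised lists and 0 of 150 unchanged ones in simulated counts. All simulated counts were drawn without correlation between genes and without a library lying apart from its group, as vehicle 1 does in the real data. The recovered and false shares of edgeR, DESeq2 and camera may therefore not hold for these libraries.

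Alternatives were DESeq2 size factors, upper-quartile scaling, the DESeq2 1.42.0 Wald test, limma voom with and without sample quality weights, no filter and a filter of 5 CPM in 3 libraries, an adjusted p under 0.10, a fold of at least 2, scaling without haemoglobin genes (of which 0 adult globin genes were in the table) or without the 10 most abundant genes, the replicate number as a block, and each library left out. For lists, camera on ranks was added, and for scores a prior of 0.1 and of 5. DESeq2 with each library left out was chosen after seeing the data. A list under an alternative counts as reversed when the direction of its set test turns. The sign of its median was tried in place of that after the values were seen, then dropped, and both counts are given in the closing section. Gene positions are from GENCODE M21 on GRCm38, the assembly also called mm10, matched by symbol for all 99 named genes.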

Results

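The study measured messenger RNA in mouse bone marrow. Whole marrow from mice lacking Dnmt3a, a DNA methyltransferase that restrains self-renewal of blood stem cells, had been transplanted into irradiated C57BL/6 recipients. The recipients then received vehicle or an inhibitor of the alpha and beta isoforms of PI3K (75 mg/kg) for 21 days before their marrow was harvested, and the treatment protocol calls the transplanted cells leukaemic. PI3K is a lipid kinase that signals growth factor input to AKT and mTOR. Each group held 3 libraries, numbered 1, 2 and 3 for vehicle and 1, 3 and 5 for the inhibitor, and the labels do not say in so many words that each came from its own mouse, so the p-values measure the spread between these libraries. Total counts over genes were 33762431, 34518818 and 59384880 in vehicles 1, 2 and 3, and 33868488, 28198638 and 35299105 in inhibitors 1, 3 and 5. The title of the series asks whether PI3K signalling carries the effect of Dnmt3a loss on blood homeostasis and myeloid skewing, and the only comparison in these libraries is inhibitor against vehicle within knockout marrow.

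Dnmt3a, the targeted gene, was read in all 6 libraries. It stood at 24.9, 17.3 and 18.9 CPM (read counts scaled to the size of the library) in vehicles 1, 2 and 3 and at 20.2, 15.4 and 15.5 CPM in inhibitors 1, 3 and 5. The log2 fold change was -0.25 ± 0.20 (SE, n = 3 per group; edgeR adjusted p = 0.486). Both groups carry the knockout, and a count over the whole gene cannot show the deletion of some exons, so these values check no label. Dnmt3a lies on chromosome 12 from 3806007 to 3914443 (GRCm38).

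Among the genes for the catalytic PI3K subunits, none passed the edgeR test over all 6 libraries. Pik3ca, which encodes the alpha isoform (chromosome 3, 32397671 to 32468486), had a log2 fold change of 0.31 ± 0.19 (SE; edgeR adjusted p = 0.383), and Pik3cb, which encodes the beta isoform (chromosome 9, 99036654 to 99140621), one of 0.48 ± 0.18 (adjusted p = 0.189). Under limma voom with quality weights Pik3cb passed, with a log2 fold change of 0.388 (adjusted p = 0.0455). That setting gave vehicle 1 a weight of 0.161 and called 1374 genes higher and 1483 lower out of 12806. Over its alternatives the adjusted p of Pik3cb ran from 0.0455 to 0.476. For Pik3cd the value was 0.23 ± 0.28 and for Pik3cg 0.21 ± 0.34. The values of Pik3cd and Pik3cg turned below 0 without vehicle 1, at -0.03 and -0.09, and that of Pik3cg also without inhibitor 1, at -0.00461. Of 40 tested PI3K, AKT and mTOR pathway components, 0 passed in the edgeR test over all genes or when adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 2 lower, against 1240 and 1524 of all 12806 tested genes. DESeq2 called 1 of the 40 lower. The median of the list was -0.00245 and its mean 0.0241 on the log2 scale, so median and test direction differ in sign (camera adjusted p = 0.826).

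With the inhibitor the macrophage genes Cd5l and Mertk fell, and the early B-cell genes Igll1 and Vpreb1, the eosinophil granule genes Epx and Prg2 and the neutrophil granule genes Camp and Elane rose. The lists these genes belong to passed the set test at its preset correlation, and had an adjusted p of 0.203 for macrophages, 0.379 for B cells and both neutrophil lists and 0.272 for basophils, mast cells and eosinophils with an estimated correlation. Vehicle 1 stood apart on the macrophage list, with a mean log2(CPM + 1) of 8.59 against 7.14 and 7.33 in vehicles 2 and 3. In the edgeR test 81 genes were higher and 153 lower with the inhibitor out of 12806 tested, with adjusted p between 0.0114 and 0.0495. Of these, 44 rose and 127 fell at least 2-fold. The groups did not overlap in any of the 234 called genes, which was also true of 30.7% of all tested genes. The average over all splits of the 6 libraries into 3 and 3 is 10%. Genes move together and the share in the other splits was not computed, so the difference from 10% is no test. The authors' deposited table gives 585 higher and 907 lower genes at its own adjusted p under 0.05. It includes 233 of the 234 called here, and the other, Arg1, has neither a p-value nor an adjusted one there. Arg1 is 1 of 15 genes without a p-value in that table, and all 15 have their highest count in vehicle 1. The numbers of genes called moved when single libraries were left out. The edgeR test called 401 higher and 633 lower without vehicle 1, 7 and 84 without vehicle 2, and 0 without any of vehicle 3, inhibitor 1, inhibitor 3 or inhibitor 5. In these last 4 fits 2398, 2174, 1832 and 2223 genes had an unadjusted p under 0.05. There DESeq2 called 373, 314, 263 and 351 higher and 742, 647, 497 and 604 lower. All 234 genes kept their direction in the edgeR fits. Since their groups do not overlap, leaving out 1 library could hardly turn a direction, so this is no support. The median size of the log2 fold changes of the 234 genes was 1.38 over all 6 libraries and 1.32 to 1.45 with 1 left out.

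Among called genes with a mean of at least 5 CPM, the largest increases were in components of the surrogate light chain of the pre-B-cell receptor. Igll1 (chromosome 16, 16860671 to 16863985) went from 2.15 ± 0.98 to 20.6 ± 12.9 CPM (SD, n = 3), a log2 fold change of 3.25 ± 0.55 (SE; edgeR adjusted p = 0.042). Its partner Vpreb1 (chromosome 16, 16868403 to 16870843) rose by 3.14 ± 0.50 and Il7r, the interleukin 7 receptor, by 1.93 ± 0.33. Without inhibitor 5 the values of Igll1 and Vpreb1 were 2.64 and 2.49. Epx, eosinophil peroxidase, rose by 2.26 ± 0.36, and Prg2, the eosinophil major basic protein, by 1.39 ± 0.22. Mcam, an adhesion molecule, rose by 1.99 ± 0.31. Mgl2, a galactose-binding lectin of myeloid cells, rose by 1.504 ± 0.210. Ldhc, a lactate dehydrogenase, and Rdh12, a retinol dehydrogenase, rose by 1.45 ± 0.18 and 1.33 ± 0.15. Camp, the cathelicidin of neutrophil granules, went from 2813 ± 710 to 7302 ± 475 CPM, a log2 fold change of 1.38 ± 0.23 (adjusted p = 0.042).

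Among called genes at the same minimum of 5 CPM, the 10 with the deepest falls included 1 member of the macrophage list, Cd5l. Arg1, arginase, fell by 6.32 ± 1.16 on the log2 scale (SE; edgeR adjusted p = 0.0473), from 78.8, 8.84 and 7.48 CPM in vehicles 1, 2 and 3 to a mean of 0.398 CPM. Cd5l, secreted by tissue macrophages (chromosome 3, 87357881 to 87371073), fell by 5.55 ± 0.75, from 653, 148 and 163 CPM in vehicles 1, 2 and 3 to 6.90 ± 3.54 CPM (SD, n = 3). Vsig4, a complement receptor of resident macrophages, fell by 4.35 ± 0.76, and Clec4f, a lectin best known from Kupffer cells, fell by 3.53 ± 0.41. Cd300e, a receptor of monocytes, fell by 4.14 ± 0.72, the chemokine gene Ccl24 fell by 4.04 ± 0.74, and the integrin gene Itga9 fell by 4.02 ± 0.59. The syndecan gene Sdc3 fell by 3.52 ± 0.61, the chemerin receptor gene Cmklr1 fell by 3.25 ± 0.58, and the potassium channel gene Kcnk13 fell by 3.16 ± 0.37. Without vehicle 1 the values were -4.37 for Arg1, -4.51 for Cd5l, -3.21 for Vsig4, -3.10 for Cd300e, -2.94 for Ccl24, -3.18 for Itga9, -2.55 for Sdc3 and -2.38 for Cmklr1.

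**Figure D1:**
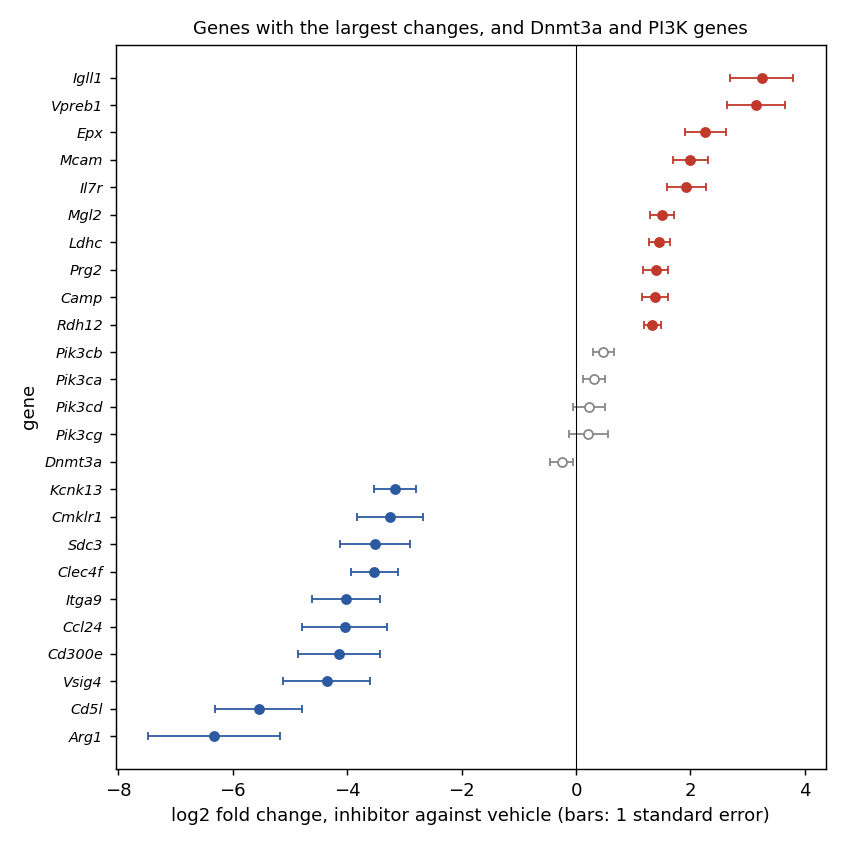
Log2 fold change of inhibitor against vehicle (x axis) for the 20 named genes with the largest changes at a mean of at least 5 CPM and for Dnmt3a and the PI3K catalytic genes (y axis), with bars of 1 standard error and 3 libraries per group. Filled points passed the edgeR test; open points did not, and they lie between -0.25 (Dnmt3a) and 0.48 (Pik3cb).

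Before the data were examined, 32 gene lists of cell types and pathways were fixed, of which 31 had members to test. Counts of members within a list stand beside 234 calls among all 12806 tested genes. At an unadjusted p under 0.05, 1240 of all tested genes were higher and 1524 lower. So 1 called member, or a few at that unadjusted p, is no result about a list. By camera with its preset correlation, 8 lists were higher and 12 lower with the inhibitor, and 11 did not pass. With an estimated correlation 0 of them passed, the smallest adjusted p was 0.176, and 5 had an unadjusted p under 0.05. Fry called 0 higher and 2 lower, the cholesterol and SREBP list (adjusted p = 0.0127) and the monocyte list (0.0175). Its adjusted p was 0.0675 for macrophage, 0.152 for B lymphoid and 0.0528 for basophil, mast cell and eosinophil genes. For late and primary granule genes of neutrophils it was 0.102 and 0.0829. Splits of the 6 libraries that mix the groups also gave up to 19 camera calls against 20 in the real split, so camera calls are given with the adjusted p of their list at an estimated correlation over all 6 libraries. Vehicle 1 stood apart from the other vehicles: its score, the mean of log2(CPM + 1) over a list, was 8.59 for macrophage genes against 7.14 and 7.33 in vehicles 2 and 3, 4.25 against 2.91 and 3.05 for stroma, and 7.81 against 6.40 and 6.502 for erythroid genes.

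All 20 macrophage genes had negative log2 fold changes, with a median of -2.58. In the edgeR test over all genes 6 fell, and 19 fell when adjusted over the list alone. Maf, a transcription factor gene active in macrophages, fell from 54.0 ± 5.10 to 21.8 ± 0.95 CPM (SD, n = 3), a log2 fold change of -1.31 ± 0.12 (SE; edgeR adjusted p = 0.0194). Spic, which drives red pulp and marrow macrophages that recycle iron, fell by 2.22 ± 0.26, and Mertk, a receptor for apoptotic cells, fell by 2.97 ± 0.38. Cd5l and Adgre1, which encodes the F4/80 antigen and fell by 1.41 ± 0.21, were also called. Camera gave the list an adjusted p of 3.39e-28, and adjusted p = 0.203 with an estimated correlation. Macrophage scores were 5.20, 5.81 and 5.60 in inhibitors 1, 3 and 5, below every vehicle (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). The median was -1.69 without vehicle 1, the library with the highest score.

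Monocyte genes had a median of -0.76 over 20 genes, and 3 fell over all genes and 9 when adjusted over the list alone. Fcgr1, a high-affinity Fc receptor, fell by 1.87 ± 0.16 (SE; edgeR adjusted p = 0.0194), the fractalkine receptor gene Cx3cr1 fell by 1.71 ± 0.17, and the lectin gene Clec4a1 fell by 1.28 ± 0.16. Csf1r, the receptor for macrophage colony-stimulating factor, had a log2 fold change of -1.72 ± 0.33 (adjusted p = 0.0529). The list had a camera adjusted p of 4.08e-11, and adjusted p = 0.176 with an estimated correlation. In the MHC class II list 1 of 12 genes passed, the transactivator Ciita, which fell by 1.49 ± 0.27, and 9 fell when adjusted over the list alone, with a median of -1.39. Cd86, Ctss and Cd74 had log2 fold changes of -1.13, -1.65 and -1.96, and without vehicle 1 of -0.802, -1.07 and -1.02. For this list camera's adjusted p was 6.72e-05, and adjusted p = 0.495 with an estimated correlation. MHC class II scores also set vehicle 1 apart, at 6.82 against 5.55 and 5.84 in vehicles 2 and 3, and the median was -0.80 without vehicle 1.

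Of 24 late granule and maturation genes of neutrophils, 1 rose over all genes, Camp, and 12 rose when adjusted over the list alone. All 24 had positive log2 fold changes (median 0.78). S100a8 and S100a9, which form calprotectin, had log2 fold changes of 1.30 ± 0.26 and 1.27 ± 0.26 (SE; edgeR adjusted p = 0.0563 and 0.0593), and Anxa1 one of 1.09 ± 0.23. In the camera test the adjusted p of the list was 5.27e-12, and adjusted p = 0.379 with an estimated correlation. Of 12 primary granule genes 1 rose over all genes and 10 when adjusted over the list alone (median 0.84). Elane, neutrophil elastase, rose by 1.03 ± 0.19 (adjusted p = 0.0463). Mpo, myeloperoxidase, had a value of 0.87 ± 0.20, Ctsg, cathepsin G, 1.01 ± 0.24, and Clec12a 0.80 ± 0.18, without passing. The set test by camera had an adjusted p of 5.75e-09, and adjusted p = 0.379 with an estimated correlation. Vehicle 1 had the lowest late granule score, 9.31 against 9.995 and 9.969 in vehicles 2 and 3.

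B lymphoid genes had a median of 1.51 on the log2 scale. Over all genes 4 of 24 rose, and when adjusted over the list alone 15 rose and 1 fell. The 4 were Vpreb1, Vpreb2, Igll1 and Il7r. Vpreb2, at 3.61 ± 0.61 (SE), is nearly identical to Vpreb1, and the counts of the 2 are uncertain where reads fit both. Vpreb2 was low, with means of 0.255 CPM in vehicle and 3.21 CPM in inhibitor libraries. Camera gave the list an adjusted p of 1.89e-10, and adjusted p = 0.379 with an estimated correlation. B lymphoid scores were 2.72, 3.16 and 3.58 in vehicles 1, 2 and 3 and 4.24, 3.78 and 5.01 in inhibitors 1, 3 and 5, and the median was 0.945 without inhibitor 5. Genes of basophils, mast cells and eosinophils had a median of 0.47, and 4 of 19 rose over all genes, against 7 up and 1 down when adjusted over the list alone. All 4 belong to eosinophil granules: Prg3 at 1.95 ± 0.23, Prg2, Epx, and Ear6 at 2.93 ± 0.47, whose counts are uncertain because the Ear genes resemble each other. Ear6 was also low, with means of 0.383 CPM in vehicle and 2.89 CPM in inhibitor libraries. For this list camera's adjusted p was 2.6e-05, and adjusted p = 0.272 with an estimated correlation. The median was 0.272 without vehicle 1 and 0.295 with the filter of 5 CPM in 3 libraries.

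T and NK cell genes had a median of -0.81 over 24 genes. Prf1, perforin, fell by 1.37 ± 0.22 (SE; edgeR adjusted p = 0.0403), while Zap70, Bcl11b and Il2rb had values of -1.11, -1.44 and -0.85 without passing. Adjusted over the list alone, 13 fell and 1 rose. In the camera test the adjusted p of the list was 6.17e-08, and adjusted p = 0.379 with an estimated correlation. In the stem and progenitor cell list 2 of 31 rose, the transcription factor gene Erg by 0.85 ± 0.11 (adjusted p = 0.0276) and the stem cell factor receptor gene Kit by 0.66 ± 0.12, and adjusted over the list alone 5 rose and 2 fell. Sox4 and Hlf had values of 1.25 ± 0.27 and 1.08 ± 0.27 without passing. The median was 0.29, the camera adjusted p 0.0136, and adjusted p = 0.272 with an estimated correlation, and camera gave 0.0524 without inhibitor 5. With the filter of 5 CPM in 3 libraries the median was 0.469. Stroma, bone and endothelium genes had a median of -0.91 with 0 of 22 called by edgeR, 0 adjusted over the list alone, 1 higher and 9 lower at an unadjusted p under 0.05, and 1 higher and 5 lower by DESeq2. Ibsp and Col3a1, of bone matrix and connective tissue, had values of -3.17 ± 0.86 and -2.70 ± 0.68, Mgp -1.93 and Cdh5 -1.77, which were -1.57, -1.62, -0.894 and -1.07 without vehicle 1. The set test by camera had an adjusted p of 0.000338, and adjusted p = 0.666 with an estimated correlation. Without vehicle 1 the stroma median was -0.35 (camera adjusted p = 0.054).

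**Figure D2:**
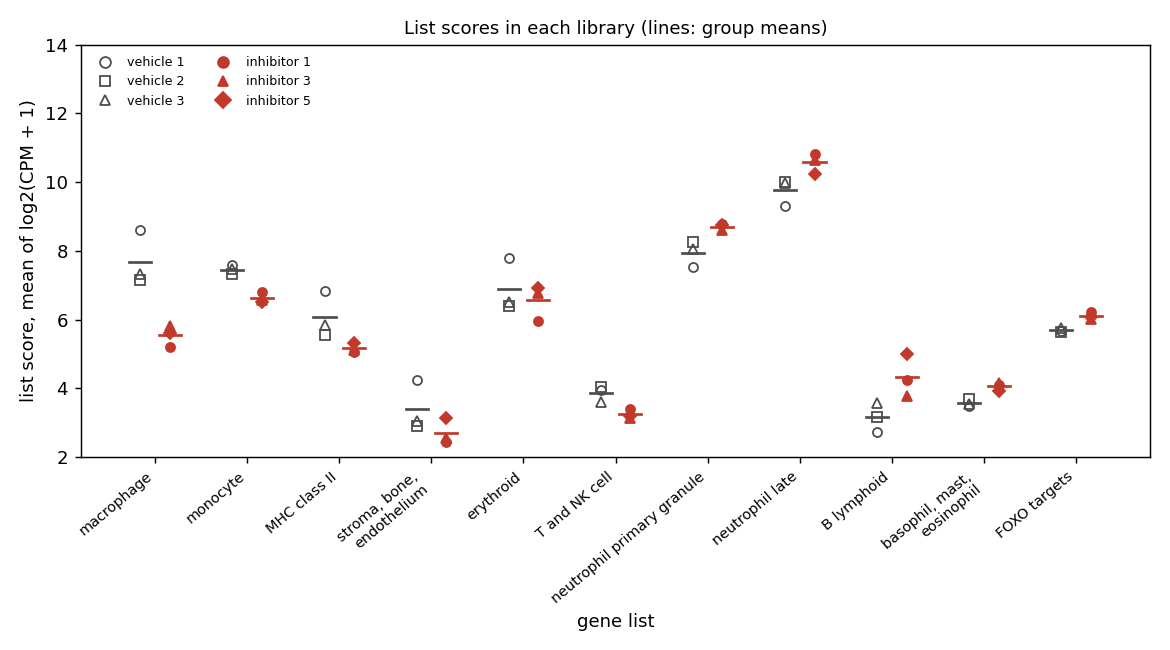
Mean of log2(CPM + 1) over the genes of 11 lists (y axis) in each library, with open grey symbols for the 3 vehicle and filled red symbols for the 3 inhibitor libraries, and lines at the group means. Macrophage scores lie between 7.14 and 8.59 in vehicle and between 5.20 and 5.81 in inhibitor libraries, and vehicle 1 is the highest vehicle library for stroma (4.25) and erythroid genes (7.81).

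Erythroid genes did not pass (median -0.39, camera adjusted p = 0.066). By edgeR 0 of 28 were called over all genes or adjusted over the list alone, with 1 higher and 1 lower at an unadjusted p under 0.05 and 1 and 1 by DESeq2. Without vehicle 1 their median was 0.23. Camera called them lower on ranks (adjusted p = 0.00487) and without vehicle 2 (median -0.638, adjusted p = 0.00213), vehicle 3 (-0.641, 0.00447), inhibitor 3 (-0.52, 0.0111) or inhibitor 5 (-0.608, 0.00489). Over all 6 libraries the list had an adjusted p = 0.878 with an estimated correlation. The adult alpha and beta globin genes have no row in the table, and 28 of the 34 listed erythroid genes do. Heme synthesis had 0 of 12 called in each of these counts (median -0.34, and 0.19 without vehicle 1; camera adjusted p = 0.389). Megakaryocyte and platelet genes had a median of 0.68 (camera adjusted p = 0.109), with 1 of 22 past the threshold, Pdgfb, which fell by 2.11 ± 0.37 (SE; edgeR adjusted p = 0.0445), and 1 up and 1 down adjusted over the list alone. The list passed on ranks (0.0238), without vehicle 1 (median 1.39, adjusted p = 0.00245) and without inhibitor 1 (median 1.08, adjusted p = 1.06e-05), and its median was 0.233 without inhibitor 5. With an estimated correlation it had an adjusted p = 0.878. In the dendritic cell list Cd209a, a C-type lectin, rose by 2.74 ± 0.27 (adjusted p = 0.0214), from 1.05 ± 0.22 to 7.06 ± 1.10 CPM (SD, n = 3). Adjusted over the list alone, 3 of its 18 genes rose and 6 fell, and the list did not pass (median -0.37, camera adjusted p = 0.247, and 0.0334 on ranks), with an adjusted p = 0.65 with an estimated correlation. Plasma cell genes had a median of -0.21 (camera adjusted p = 0.73), with 0 of 10 called over all genes and 1 lower adjusted over the list alone. At an unadjusted p under 0.05, 1 was higher and 2 lower, and DESeq2 called 1 each way.

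In all, 5 genes of the FOXO target list rose. FOXO factors are held out of the nucleus by AKT, and the list was fixed for that reason. Pik3ip1, a negative regulator of PI3K, rose from 16.7 ± 2.48 to 37.9 ± 4.36 CPM (SD, n = 3), by 1.18 ± 0.16 on the log2 scale (SE; edgeR adjusted p = 0.0323). Hbp1, a transcriptional repressor, rose by 0.84 ± 0.12, Cdkn1b, the cell cycle inhibitor p27, by 0.77 ± 0.13, and Ccng2, an atypical cyclin, by 1.09 ± 0.19. Il7r, also on the B lymphoid list, was the other. Of 31 tested genes 9 rose and 2 fell when adjusted over the list alone, and the median was 0.32. Camera gave the list an adjusted p of 6.53e-05, and adjusted p = 0.272 with an estimated correlation. FOXO scores were 5.67, 5.63 and 5.77 in vehicles 1, 2 and 3 and 6.23, 6.01 and 6.06 in inhibitors 1, 3 and 5.

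Cholesterol synthesis and SREBP targets had a median of -0.35 over 31 genes. Over all genes 1 fell in the edgeR test, and 7 fell when adjusted over the list alone. Sqle and Insig1 had log2 fold changes of -1.21 ± 0.26 and -0.61 ± 0.17 (SE) without passing. For this list camera's adjusted p was 5.67e-06, and adjusted p = 0.176 with an estimated correlation. In the list for ATF4 and amino acid metabolism 2 of 29 passed: the mitochondrial folate enzyme gene Mthfd2 fell by 0.64 ± 0.10 and Nupr1 fell by 1.28 ± 0.22. Slc7a5, an amino acid transporter, and Atf5 had values of -1.25 and -0.63 without passing. Adjusted over the list alone, 11 fell and 1 rose (median -0.54). In the camera test the adjusted p of the list was 8.74e-06, and adjusted p = 0.381 with an estimated correlation. Without vehicle 1 the ATF4 median was -0.33.

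Immediate early and heat shock genes had a median of -0.62, and 2 of 22 passed: Egr1 fell by 2.96 ± 0.47 (SE; edgeR adjusted p = 0.0403) and Fosb fell by 1.89 ± 0.35. Fosb was low throughout, with means of 1.40 CPM in vehicle and 0.376 CPM in inhibitor libraries. Adjusted over the list alone 5 fell. The set test by camera had an adjusted p of 6.09e-05, and adjusted p = 0.379 with an estimated correlation, and the median was -0.30 without vehicle 1 and -0.375 with the filter of 5 CPM in 3 libraries. In the inflammatory and NF-kB list Icam1 fell by 1.05 ± 0.16 and Ptgs2 fell by 2.85 ± 0.52 (-2.23 without vehicle 1), while Clec4e, a receptor for mycobacterial glycolipid, rose by 0.86 ± 0.15. Ptgs2 had means of 3.88 CPM in vehicle and 0.535 CPM in inhibitor libraries. Adjusted over the list alone, 6 of 26 fell and 2 rose (median -0.38, camera adjusted p = 0.0107), and adjusted p = 0.65 with an estimated correlation. The camera call was lost with the filter of 5 CPM in 3 libraries (median -0.256, adjusted p = 0.325) and without inhibitor 5 (0.0809), and the median was -0.22 without vehicle 1. Interferon response genes had a median of -0.46, with 1 of 38 past the threshold over all genes, Irf7, which fell by 1.20 ± 0.22, and 2 adjusted over the list alone. Camera gave the list an adjusted p of 6.55e-05, and adjusted p = 0.666 with an estimated correlation. Without vehicle 2 the interferon list did not pass (median -0.11, camera adjusted p = 0.15), and its median was -0.80 without inhibitor 1.

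Cytosolic ribosomal protein genes had positive values in 53 of 54, with a median of 0.38. By edgeR 0 were called over all genes or adjusted over the list alone, 16 were higher at an unadjusted p under 0.05, and DESeq2 called 2 higher. Ribosomal scores overlapped between the groups, at 8.94 in vehicle 1 and 8.83 in inhibitor 1 (exact two-sided permutation p = 0.2). Of the other lists that camera called, oxidative phosphorylation, MYC, unfolded protein response, interferon, NF-kB and stroma also had overlapping scores. Rps9 and Rps24 had values of 0.63 ± 0.15 and 0.74 ± 0.24 (SE), and ribosomal protein genes have many processed copies, which leaves their counts uncertain. For this list camera's adjusted p was 5.75e-09, and adjusted p = 0.65 with an estimated correlation. Oxidative phosphorylation genes had a median of 0.16 with 0 of 52 called by edgeR, 0 adjusted over the list alone, 8 higher at an unadjusted p under 0.05, and 0 by DESeq2. Atp5e and Atp5h had values of 0.55 and 0.48. In the camera test the adjusted p of the list was 0.0344, and adjusted p = 0.878 with an estimated correlation. The camera call was also lost with the filter of 5 CPM in 3 libraries (0.0724) and without vehicle 3 (median 0.0616, adjusted p = 0.496), inhibitor 3 (0.0613) or inhibitor 5 (0.0745, 0.414), and the median was 0.261 without inhibitor 1. Genes for MYC and ribosome biogenesis had a median of -0.29, with 0 of 30 called by edgeR, 0 adjusted over the list alone, 7 lower at an unadjusted p under 0.05, and 0 by DESeq2. Nop2 and Noc4l had values of -0.48 and -0.46. The set test by camera had an adjusted p of 0.00415, and adjusted p = 0.695 with an estimated correlation, and without inhibitor 1 the median was -0.148 and camera gave 0.216. The unfolded protein response list had a median of -0.27, with 0 of 20 called by edgeR over all genes and 2 lower adjusted over the list alone. At an unadjusted p under 0.05, 2 were higher and 4 lower, and DESeq2 called 1 and 3. Atf6 had a value of -0.59 ± 0.11 and Dnajb9 one of 0.38 ± 0.11. Camera gave the list an adjusted p of 0.0241, and adjusted p = 0.65 with an estimated correlation. That call was lost without vehicle 2 (0.192), vehicle 3 (0.135), inhibitor 3 (0.105) or inhibitor 5 (0.0644).

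Cell division genes showed no call. Mitosis genes had a median of -0.02 (camera adjusted p = 0.908), and 0 of 28 passed by edgeR over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2. DNA replication genes had a median of -0.00589 and a mean of 0.0406, which differ in sign (camera adjusted p = 0.624), with 0 of 32 called by edgeR, 0 adjusted over the list alone, 2 higher at an unadjusted p under 0.05, and 0 by DESeq2. Without inhibitor 1 the replication list passed camera (median 0.14, adjusted p = 0.0111), and over all 6 it had an adjusted p = 0.932 with an estimated correlation. Glycolysis genes had a median of -0.10 (camera adjusted p = 0.826), with 0 of 22 called by edgeR, 0 adjusted over the list alone, 1 higher and 2 lower at an unadjusted p under 0.05, and 0 by DESeq2. For p53 targets the median was -0.09 (camera adjusted p = 0.462), with 0 of 20 called over all genes, 1 up and 2 down adjusted over the list alone, 3 higher and 4 lower at an unadjusted p under 0.05, and 1 and 2 by DESeq2. The DNA methylation machinery, which includes Dnmt3a, had a median of -0.04 (camera adjusted p = 0.908), and 0 of 16 passed by edgeR over all genes, adjusted over the list alone, at an unadjusted p under 0.05 or by DESeq2.

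**Figure D3:**
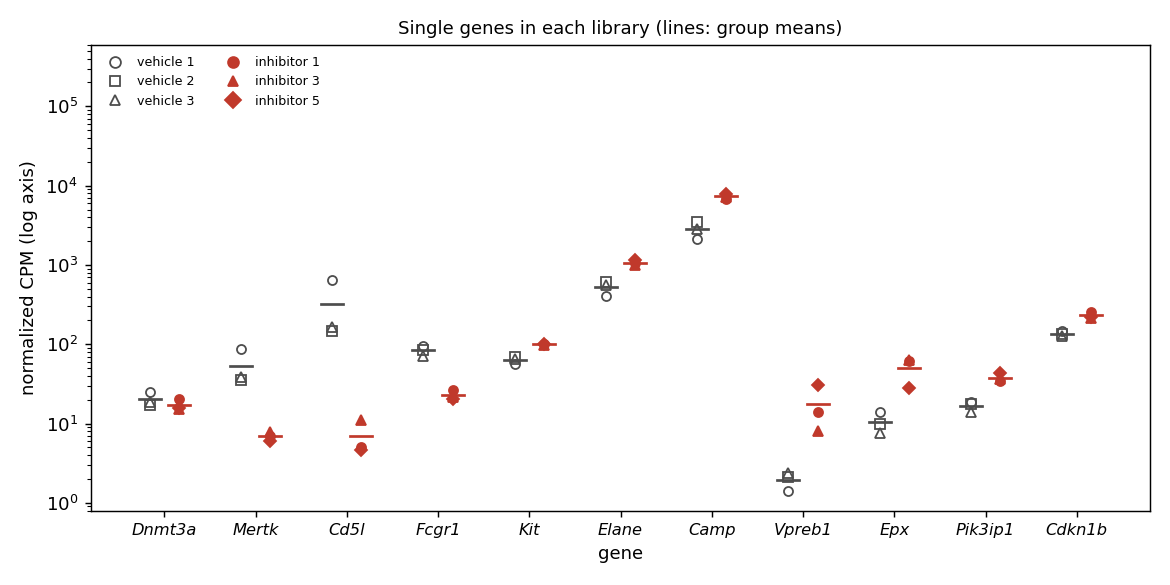
Normalized CPM on a log axis (y axis) of 11 genes in each library, with open grey symbols for the 3 vehicle and filled red symbols for the 3 inhibitor libraries, and lines at the group means. The groups do not overlap for any of these genes except Dnmt3a; Mertk has means of 53.8 and 6.87 CPM and Camp means of 2813 and 7302 CPM.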

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

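The DESeq2 fits with single libraries left out were chosen after the data were seen. Over the alternatives, 1212 of 1671 values of the 99 named genes kept direction and side of the threshold, 311 lost the call, 143 gained one and 5 reversed. All 234 called genes kept their direction wherever they were tested in the edgeR and voom fits and in DESeq2 on all 6 libraries. Their groups do not overlap, so another setting or a library left out could hardly have turned them. The counts moved far more. Genes higher and lower were 598 and 911 with the DESeq2 Wald test, 30 and 55 with limma voom, 1374 and 1483 with voom quality weights (which gave vehicle 1 a weight of 0.161), 422 and 634 at an adjusted p under 0.10, and 44 higher with a fold of at least 2. Without single libraries edgeR gave 0 to 401 higher and 0 to 633 lower, and DESeq2 263 to 893 and 497 to 983, the highest of each without vehicle 1. Removing vehicle 1 lowered the biological coefficient of variation from 25.2% to 15.5%. The cause of the moves in these counts was not tested. The numbers 1 and 3 are shared by the groups, but no label says that they pair mice, so the main fit has no block. The deviations of same-numbered libraries correlated at -0.514 and -0.103. For libraries with different numbers these correlations ran from -0.476 to 0.505, so the check cannot show whether mice were paired. With the replicate number as a block edgeR called 0 higher and 7 lower genes, with 1438 at an unadjusted p under 0.05. Vehicle 2 and inhibitor 5 are alone in their blocks there, so the contrast rests on vehicles 1 and 3 and inhibitors 1 and 3.

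Lists higher and lower numbered 0 and 0 with an estimated correlation and 0 and 2 with fry. Over 372 pairs of list and setting the direction of the set test turned in 22 and the sign of the median in 16, in none of them for 1 of the 20 called lists. Under voom quality weights Pik3cb passed (0.388), and Pik3cd and Pik3cg were -0.0253 and -0.0749. Without single libraries the values of Pik3cd and Pik3cg ran from -0.0280 to 0.441 and -0.0883 to 0.421. For lists whose set test or median turned in at least 1 setting, the medians ran, without single libraries, from -0.641 to 0.228 (erythroid), 0.233 to 1.39 (megakaryocyte), -0.547 to 0.194 (heme), -0.0787 to 0.142 (DNA replication), -0.359 to 0.0993 (plasma cell), -0.125 to 0.027 (glycolysis), -0.0263 to 0.0215 (PI3K components), -0.0828 to -0.00371 (DNA methylation) and -0.111 to 0.0225 (mitosis). The replicate block draws its contrast without vehicle 2 and inhibitor 5. With it the medians were -0.0368 for megakaryocyte, -0.117 for DNA replication, 0.00954 for glycolysis, 0.0443 for DNA methylation and 0.0221 for mitosis. The DNA methylation score difference was -0.00579 with a prior of 0.1 and -0.00159 with a prior of 5. None of these genes and lists passed the edgeR test or camera at its preset correlation on all 6 libraries without the block, but camera on ranks called erythroid (0.00487) and megakaryocyte (0.0238), and the replicate block erythroid (median -0.767, adjusted p = 2.71e-06) and heme (-0.678, 0.00525), where an estimated correlation on all 6 libraries gave erythroid and megakaryocyte an adjusted p of 0.878 and heme one of 0.932. With that block interferon (0.698), stem and progenitor (0.144), unfolded protein response (0.456) and oxidative phosphorylation (0.396) did not pass. The alternative for normalized values was not run because the table holds counts. Leaving out haemoglobin genes removed 1 tested gene, tests nothing here and is not in these counts.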

Other observations

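The genes in the first 2 paragraphs were chosen after their values were seen, as were the tests of explanations, while the splits of the libraries and the fits without vehicle 1 had been planned. The purinergic receptor gene P2rx7 fell by 1.63 ± 0.13 on the log2 scale (SE, n = 3 per group; edgeR adjusted p = 0.0114), and P2ry6 and P2ry12 fell by 2.21 ± 0.32 and 1.91 ± 0.33. Ctsc, the cathepsin that activates granule serine proteases, fell from 745 ± 43.8 to 262 ± 42.1 CPM (SD, n = 3), the opposite direction to Elane. Ctsz, the lysosomal reductase gene Ifi30 and the acid lipase gene Lipa fell by 1.15 ± 0.15, 1.36 ± 0.17 and 0.95 ± 0.15. The complement genes C2 and C3ar1 fell by 2.35 ± 0.34 and 2.58 ± 0.37. Tnfrsf11a, which encodes the osteoclast receptor RANK, fell by 2.66 ± 0.32, and Ocstamp, needed for osteoclast fusion, fell by 4.12 ± 0.65 (-3.36 without vehicle 1). Ocstamp had a mean under 5 CPM. Nr1h3, the oxysterol receptor LXR alpha, fell by 2.08 ± 0.23.

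Gfi1, a repressor needed for neutrophil differentiation, rose by 1.12 ± 0.17 (SE; edgeR adjusted p = 0.0402). The splicing kinase genes Clk1 and Clk4 rose by 1.00 ± 0.13 and 0.78 ± 0.11. Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 176 ± 5.64 to 304 ± 31.3 CPM (SD, n = 3), and Pdcd4, a translation inhibitor degraded downstream of mTOR, rose by 0.77 ± 0.13. Dusp6 and Spred1, whose products dampen ERK signalling, fell by 1.14 ± 0.19 and 1.20 ± 0.14.

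The real split of the libraries called 234 genes and the highest of the other 9 called 0. For lists the real split called 20 and the highest other 19. In each case 1 of the 10 splits gave as many, the real one, and 10 splits cannot give a share under 0.05. Every other split called at least 11 lists by camera at its preset correlation. Those splits mix the groups unevenly, so part of the difference between inhibitor and vehicle stays in them. Members can also move together more than the preset 0.01 allows (estimated correlation 0.516 for macrophage). The source of these calls was not tested.

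The first pattern is the lower macrophage list. Vehicle 1 alone does not account for it, since without that library the median was -1.69. A poorer recovery of tissue-bound marrow cells of every kind would lower stroma as much. Without vehicle 1 the stroma median lay above the macrophage median by 1.34 ± 0.26 (SE across members). That error treats genes as independent, though members move together (estimated correlation 0.516 for macrophage and 0.916 for stroma over all libraries). It does not measure the spread between libraries, so the smaller fall of stroma speaks against an equal loss without settling the question. Fewer macrophages with the same expression per cell may account for the lower macrophage list, but the test did not decide. That reading predicted no departure from the list mean. When adjusted over the list, 1 member, Cd5l, fell by more (departure -2.93 on the log2 scale), and Vcam1 and Slc40a1 fell by less. Other cells that express Vcam1 and Slc40a1 could produce the smaller falls, while the larger fall of Cd5l is left unexplained. Bulk RNA keeps that reading open, and it cannot be told apart here from lower expression per macrophage. The inhibitor, as the design's own difference, also stays open.

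The second pattern is the higher FOXO target list. Of its 31 tested members 2 are shared with the lymphoid lists, and leaving out 2 of 31 could move little. The median was 0.316 over all 31 and 0.279 over the 29 on neither list, so shared genes account for little of that median. In the test of shared genes, the 29 had a camera p of 0.000434 and a p of 0.0956 with an estimated correlation, which decides nothing more. A larger share of neutrophils cannot be told apart from the rise of the FOXO list. The median of all 31 tested members minus the late neutrophil median was -0.463 ± 0.164 (SE across members). A smaller rise decides nothing because other marrow cells can express these genes. Both tests of this list were changed after their first results were seen: the neutrophil test had run on the 5 called members, of which 2 rose by over 2 standard errors more than the late neutrophil median, and the test of shared genes had used the preset correlation alone. An effect of the inhibitor on FOXO activity is a hypothesis that these counts do not separate from a change in cell types.

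The third pattern is that vehicle 1 lay apart from vehicles 2 and 3. Its position on the first principal component was -64.4, against -2.15 and -6.85 for vehicles 2 and 3 and 17.0 to 35.2 for the inhibitor libraries. Depth does not account for it, as the totals of vehicles 1 and 2 differed by 2.24%. A swap with an inhibitor library would need a partner, and 0 inhibitor libraries had a macrophage score in the vehicle range. These scores were known when that check was chosen and already separate the groups as labelled, so it cannot exclude a swap. A lower share of neutrophils alone would raise the other cell types alike, yet its B lymphoid score was -0.648 from the mean of vehicles 2 and 3 while its macrophage score was 1.36 above. A difference in how the marrow was sampled, a single wrong label and a difference between recipients were not tested and stay open.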
